A study of Homo sapiens with 4 samples.

How the data were processed

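RNA from RCC4 cells was measured by RNA sequencing in 4 libraries, 2 from cells given a control hairpin (shControl) and 2 from cells given a hairpin against MIRE (shMIRE), all collected on day 3. Per the labels' protocols, the hairpins were delivered with lentiviruses, the medium held 10% serum, and polyadenylated RNA from 1 µg of total RNA was made into libraries with an Illumina TruSeq kit and selected for fragments of 370 to 420 bp. The titles number the libraries 1 and 2 in each group. Nothing in the labels says that equally numbered libraries share a batch, or that the libraries of a group came from separate infections, so p-values measure the spread between these libraries, which may be technical.

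Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and genome build hg38 were used, with no role or order given for any of them. The values the authors deposited are whole numbers from 0 upward for the same 1176 genes, in the same order, in all 4 tables. Among these genes the ratio of the group means ended at 2 in both directions: the smallest was 2.00 among genes higher in shMIRE and, taken as shControl over shMIRE, also 2.00 among genes lower in it, and 2 genes lay just under a fold of 2. The median ratio of replicate 2 to replicate 1 was 1.02 in shControl and 1.01 in shMIRE with no rescaling. The deposited values were therefore handled as a score, a read count per gene that looks already scaled between libraries and rounded, and not as raw counts. The scaling method and the rule by which genes entered the tables are not given in the sources used here.

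The tables thus hold genes chosen for a difference between the groups. The number of genes past a threshold is no share of the transcriptome, p-values for single genes are not independent evidence of a change, and genes outside the tables were not analysed here. The listed values summed to 2476944 and 2514039 in shControl replicates 1 and 2 and to 2043204 and 2002994 in shMIRE replicates 1 and 2. These sums cover the listed genes only. The depth of the whole libraries is unknown, so no counting interval or detection floor is given, and a gene at 0 is said to be listed at 0.

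Gene IDs were matched to symbols for 1175 of the 1176 genes. GENCODE 29, on the GRCh38 (hg38) assembly, annotates 1172 of them as protein-coding and 2 as another type, and 2 IDs were not in it. Coordinates are 1-based and come from that release unless another is named.

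The test chosen before the data were examined was a count test, with limma-trend as the fallback for normalised values. The fallback was used. Values were taken as log2(value + 1), so the fold change of a low gene is understated on that scale, genes with a mean value above 1 were kept (all 1176), and groups were compared with limma 3.58.1 in R 4.3.3, without covariates. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Folds in the text are ratios of group means of the deposited values, and standard errors belong to limma's log2 fold change. On simulated data for 1176 genes, with 200 changed genes and 2 libraries per group, this fit called 88% of 2-fold changes, 95% of 4-fold changes and 0.102% of unchanged genes, and 0 calls had the wrong sign. Most simulated genes were unchanged, whereas the deposited genes were chosen for a difference, so these rates do not carry over to them.

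Before the data were examined, 30 gene lists with 677 distinct genes were fixed for pathways, kidney and other cell types, histones and mitochondrial mRNAs. Lists with at least 5 listed members (8 lists) were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01. Its background was the listed genes only, so a list test asks whether the direction and size of a list differ from those of other changed genes. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera tests on the residual degrees of freedom of the fit, which are few with 4 libraries, so it passes fewer lists. The genes named in the text follow a rule fixed at the same time: the 12 largest rises and the 12 largest falls in log2 fold change among genes past the threshold with a mean value of at least 5 and no overlap between the groups, and the 3 members of each list with the smallest p. Other genes are named as members of a list, or are said to be chosen after their values were seen.

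Alternatives fixed beforehand were quantile normalisation, limma without its intensity trend, no filter, a filter of mean value above 5, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, and stricter thresholds. Scaling the libraries to equal sums of the listed values was added after the data were seen.

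The sequence comparison was also chosen after the data were seen. For each listed gene the longest annotated 3′ UTR of a protein-coding transcript, of at least 20 bases, was taken from GENCODE 29 (1163 genes). All 16384 heptamers were scored for presence in genes lower against genes higher in shMIRE with a Mantel-Haenszel z over 10 strata of 3′ UTR length, and directions were shuffled within strata 1000 times. On simulated directions over the same 1163 sequences, a planted heptamer ranked first in 100 of 100 simulations. The planted heptamers were about as frequent, and their effects about as large, as for the heptamer reported below. The simulations therefore do not show how a rarer heptamer or a smaller effect would rank. Differences of medians were tested with 100000 permutations, and shares of genes carry 95% Wilson intervals. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.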

Results

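RCC4 is a line of human clear cell renal carcinoma cells that lack functional VHL, so that hypoxia-inducible factors stay active in them at normal oxygen. The libraries compared RCC4 cells with a hairpin against MIRE (shMIRE, n = 2) and cells with a control hairpin (shControl, n = 2) on day 3, to ask which transcripts differ when MIRE is depleted. The labels give no identifier for MIRE, which was taken to be SAP30-DT because RefSeq lists the name as its synonym. SAP30-DT is a long non-coding RNA gene of 21468 bp on chromosome 4 from 173349231 to 173370698 (GRCh38.p14). In GENCODE 29 its neighbours are SAP30 (173369969 to 173377532, plus strand) and HMGB2 (173331695 to 173335125, minus strand). The level of MIRE itself was not analysed here, so the depletion was not checked in these libraries. The tables hold 1176 genes that the authors listed with at least about a 2-fold difference between the groups, with values that look normalised and rounded. Listed values summed to between 2002994 and 2514039 per library.

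In shMIRE cells, all 12 listed targets of NF-kB and 7 of 8 listed genes of the extracellular matrix were higher. Lower were 6 of 7 listed genes of the integrated stress response and all 3 listed genes each of cholesterol synthesis and DNA replication. The stress response list did not differ from the other listed genes with camera (adjusted p = 0.145). The cholesterol and replication lists were too short to test, and 60.6% of all listed genes were lower. The chemokine gene CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203) rose from 716 ± 5.66 in shControl to 3452 ± 21.2 in shMIRE (SD, n = 2), 4.82-fold. SLC7A5 (ENSG00000103257, chromosome 16, 87830023 to 87869488), which encodes the amino acid transporter LAT1, fell from 76206 ± 649 to 27147 ± 392 (SD, n = 2), 2.81-fold. Of the 1176 listed genes, 463 had a higher mean and 713 (60.6%) a lower mean in shMIRE. With limma, 453 rose and 694 fell at an adjusted p under 0.05, and 29 did not pass. Because the genes were listed for their difference, these counts describe the list and not the whole transcriptome.

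**Figure D1:**
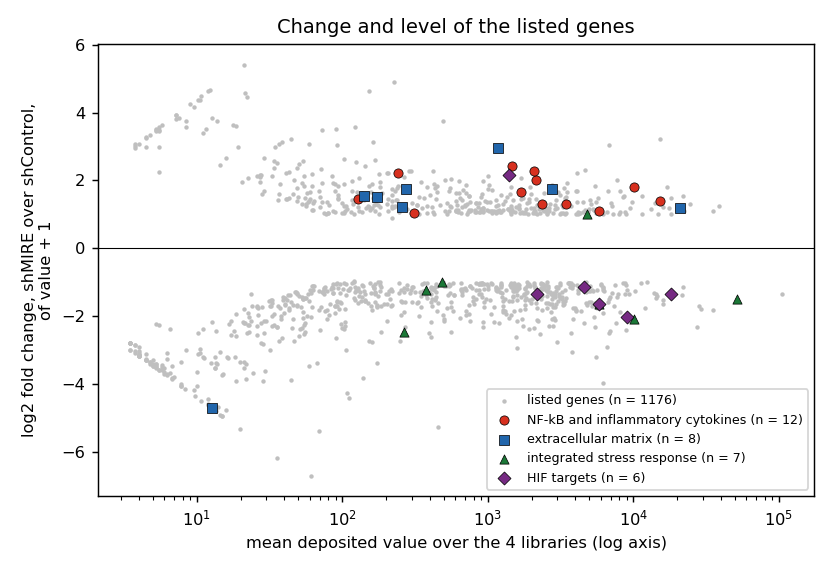
Each point is 1 of the 1176 listed genes, with the mean deposited value over the 4 libraries on a log x axis and the log2 fold change of value + 1, shMIRE over shControl, on the y axis; coloured symbols mark members of 4 gene lists. All 12 listed NF-kB genes lie above 0, and 5 of the 6 listed HIF targets lie below it.

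Targets of NF-kB and inflammatory cytokines stood apart from the other listed genes. Of the 27 genes of this list, 12 were listed, and 12 of 12 rose. CCL2, ICAM1, which encodes an adhesion molecule for leukocytes, and TRAF1, an adaptor of TNF receptors, had the smallest p-values. ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615) rose from 8407 ± 412 to 22261 ± 674 (SD, n = 2), 2.65-fold, and TRAF1 rose 4.02-fold to 3438 ± 209. The cytokine genes CSF2 and IL6 rose 5.35-fold and 2.45-fold, the adhesion gene VCAM1 3.50-fold, and the chemokine gene CXCL1 3.19-fold. The list differed from the remaining listed genes with camera (adjusted p = 8.4e-05), though not with an estimated correlation (adjusted p = 0.316 with an estimated correlation, range over the camera alternatives 8.5e-06 to 0.316).

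Matrix, mesenchymal and YAP/TEAD genes were mostly higher as well. These lists share listed genes, so their results are not separate. MMP2 is in the matrix and epithelial-mesenchymal lists, and AXL and TGFB2 are in the epithelial-mesenchymal and YAP/TEAD lists. COL1A1 of the matrix list and CCN2 of the YAP/TEAD list are also in the TGF-beta list below. Of 36 extracellular matrix genes, 8 were listed: 7 rose and 1 fell (camera adjusted p = 0.0113). The gelatinase gene MMP9 rose 7.75-fold, from 271 ± 7.07 to 2101 ± 155 (SD, n = 2), COL1A1, the collagen I alpha 1 chain, rose 3.33-fold, and the membrane protease gene MMP14 rose 2.29-fold to 29023 ± 821. TIMP3, an inhibitor of matrix proteases, was listed at 21 and 30 in the shControl libraries and at 0 in both shMIRE libraries. Of 24 genes of the epithelial-mesenchymal transition, 5 were listed and 5 rose (camera adjusted p = 0.0113), among them ITGA5, the integrin alpha 5 subunit (2.94-fold, to 32639 ± 1068), AXL, a receptor tyrosine kinase (2.40-fold, to 55134 ± 1710), and ITGB3, the integrin beta 3 subunit (2.02-fold). Of 22 YAP/TEAD targets, 6 were listed, 5 rose and 1 fell (camera adjusted p = 0.0202), with NT5E, an ectonucleotidase, up 4.92-fold and CRIM1 up 2.14-fold. With an estimated correlation none of these 3 lists passed: the adjusted p was 0.448 for extracellular matrix (range over the camera alternatives 0.0102 to 0.448), 0.316 for the epithelial-mesenchymal transition (0.0102 to 0.316) and 0.316 for YAP/TEAD targets (0.0182 to 0.316). The estimated correlation was 0.651, -0.193 and -0.166 in that order, against the preset 0.01.

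The remaining lists with at least 5 listed members did not pass with camera. Of 20 TGF-beta targets, 5 were listed, 4 rose and 1 fell (camera adjusted p = 0.0510, or 0.0290 with the replicate number as a block and 0.0452 with equal sums of the listed values; adjusted p = 0.448 with an estimated correlation), with LTBP2, a latent TGF-beta binding protein, up 3.77-fold and CCN2, a matricellular growth factor, up 2.27-fold. Of 25 genes of MAPK/ERK output, 7 were listed, 5 rose and 2 fell (camera adjusted p = 0.117). The AP-1 subunit gene FOSL1 rose 2.45-fold to 35168 ± 2333, and CCND1, which encodes cyclin D1, fell 4.06-fold, from 14627 ± 701 to 3602 ± 68.6 (SD, n = 2). Of 38 HIF targets, 6 were listed, 1 rose and 5 fell (camera adjusted p = 0.145): NDRG1 fell 2.52-fold from 26202 ± 216, and the glucose transporter gene SLC2A3 rose 4.50-fold to 2300 ± 169. Of 23 genes of the integrated stress response, 7 were listed, 1 rose and 6 fell (camera adjusted p = 0.145). Besides SLC7A5, the pseudokinase gene TRIB3 fell 4.23-fold from 16275 ± 1215, and the mTORC1 inhibitor gene DDIT4 fell 3.09-fold.

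**Figure D2:**
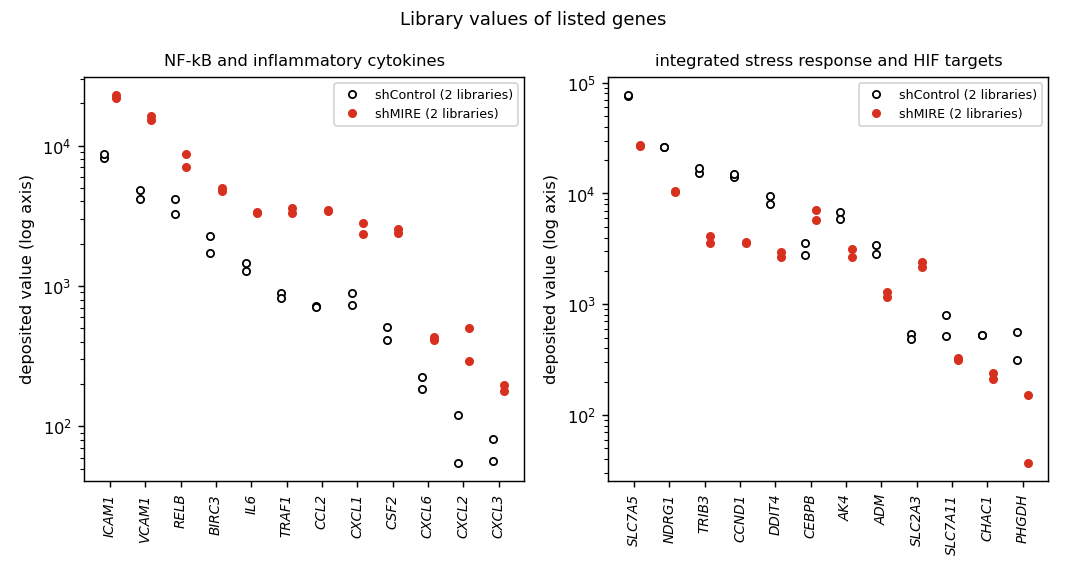
Deposited values per library on log y axes, open circles for the 2 shControl and filled circles for the 2 shMIRE libraries, for the 12 listed NF-kB genes and for the listed genes of the integrated stress response and HIF lists. In the left panel both shMIRE values lie above both shControl values for all 12 genes; in the right panel CEBPB and SLC2A3 are higher and the other genes lower in shMIRE.

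Lists with fewer than 5 listed members were not tested as lists, and their counts describe the listed members only. Of 24 cholesterol synthesis genes, 3 were listed and 3 fell, among which the sterol isomerase gene EBP fell 4.60-fold from 7541 ± 233 and IDI1, an isomerase of the isoprenoid pathway, fell 3.65-fold. The glycolysis list had 1 listed gene of 20, TPI1, triosephosphate isomerase, which fell 4.94-fold from 45646 ± 1865 to 9233 ± 48.1 (SD, n = 2). Of 27 genes of DNA replication and G1/S, 3 were listed and 3 fell: FEN1, the flap endonuclease, fell 9.07-fold from 9999 ± 235 to 1102 ± 5.66, POLA1, DNA polymerase alpha, fell 2.78-fold, and the phosphatase gene CDC25A fell 2.33-fold. The 1 listed gene of 26 in the list of MYC and ribosome biogenesis, SRM, spermidine synthase, fell 4.99-fold. The 1 listed gene of 28 for oxidative phosphorylation, NDUFB8, fell 2.67-fold, and of 25 autophagy and lysosome genes the listed ATG9A and CTSL fell 3.17-fold and 3.31-fold. Of 23 NRF2 targets, TXNRD1 fell 3.27-fold and SLC7A11, the cystine transporter, 2.04-fold. Of 24 genes of fatty acid synthesis and lipid storage, ACSL3 fell 3.09-fold and DGAT2 rose 2.72-fold. The 1 listed m6A gene of 21, IGF2BP1, fell 3.05-fold. Leaving out 1 library ended the calls of CDC25A (adjusted p of 0.0614 and 0.0843 without shControl replicate 1 or 2), SLC7A11 (0.132 and 0.140 without shMIRE replicate 1 or 2), IGF2BP1 (0.109, 0.172 and 0.0880 without shControl replicate 1, shControl replicate 2 or shMIRE replicate 1) and DGAT2 (0.0828, 0.130 and 0.125 without shControl replicate 2, shMIRE replicate 1 or shMIRE replicate 2), all with limma.

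Of 22 p53 targets, 3 were listed and 3 rose: TNFRSF10B, the TRAIL receptor DR5, rose 2.59-fold to 14147 ± 136, FAS 2.15-fold and BTG2, an antiproliferative gene, 2.06-fold. Of 24 apoptosis regulators, 3 were listed and 3 rose: the BH3-only genes BIK and PMAIP1 rose 4.73-fold and 2.44-fold, and BIRC3, an inhibitor of apoptosis and NF-kB target, rose 2.43-fold. Of 33 genes of the type I interferon response, 3 were listed and 3 fell. OAS3, an oligoadenylate synthetase, fell 3.34-fold from 8726 ± 55.9 to 2611 ± 120, OAS2 fell 4.29-fold, and OASL was listed at 32 and 26 in shControl and at 0 in both shMIRE libraries. The 1 listed gene of 20 of the ER unfolded protein response, the chaperone gene DNAJB9, rose 3.05-fold. With limma, the adjusted p of OAS2 was 0.0621 and 0.0805 without shMIRE replicate 1 or 2 and 0.0833 with quantile normalisation, and that of BIRC3 was 0.0515 without shMIRE replicate 1.

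Markers of cell type moved both ways. Of 23 genes of epithelial identity, ELF3, an epithelial transcription factor, fell 2.98-fold and CLDN1, a tight junction claudin, rose 2.48-fold. Of 23 proximal tubule markers, MIOX, the inositol oxygenase of kidney, rose 2.14-fold to 1443 ± 168, and LRP2, megalin, was listed at 6 and 18 in shControl and at 0 in both shMIRE libraries. The 1 listed leukocyte marker of 18, ITGAM, rose 2.39-fold, from 63.0 ± 14.1 to 150.5 ± 6.36. Of 14 endothelial markers, ROBO4 rose 5.48-fold to 241 in each shMIRE library, and FLT1 was listed at 3 and 11 in shControl and at 0 in shMIRE. Of 14 fibroblast markers, COL1A1 and COL6A3 rose 3.33-fold and 3.38-fold, and PDPN was listed at 13 and 38 in shControl and at 7 and 0 in shMIRE (limma adjusted p = 0.0482). Without shMIRE replicate 1 or 2, limma's adjusted p was 0.0852 and 0.0741 for ITGAM (0.0756 without shControl replicate 2), 0.0679 and 0.0659 for LRP2, 0.111 and 0.108 for FLT1, and 0.0780 and 0.0549 for MIOX. For PDPN it was 0.197, 0.355 and 0.234 without shControl replicate 1, shControl replicate 2 or shMIRE replicate 2, 0.0932 without the intensity trend, 0.0935 with a pseudocount of 0.1 and 0.0502 with equal sums of the listed values. With quantile normalisation it was 0.178 for LRP2, 0.538 for FLT1 and 0.195 for PDPN. Of 22 histone genes, 4 were listed and 4 fell, but limma's adjusted p was 0.0568 and 0.0509 for H2AC6 without shControl replicate 1 or 2, and 0.0702, 0.0769 and 0.0554 for H2BC21 without shControl replicate 1, shMIRE replicate 1 or shMIRE replicate 2. Of the 30 mitosis and G2/M genes, the 28 cytosolic ribosomal protein genes and the 13 mitochondrially encoded mRNAs, 0 were listed. In all, 85 of the 677 distinct genes of the fixed lists were listed, 85 passed over all genes tested and 85 adjusted over the list alone, 46 up and 39 down.

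The largest changes on the log2 scale belonged to low genes and to genes that overlap others. Among the 12 largest rises, 10 genes were listed at 0 in both shControl libraries, including SLAMF8 (36 and 48 in shMIRE) and CD33 (22 and 27), which encode receptors of myeloid cells, and KRT2 (21 and 27), a keratin. KCNF1, a potassium channel subunit, stood at 0 and 2 in shControl and at 30 and 54 in shMIRE. Among the 12 largest falls, 10 genes were listed at 0 in both shMIRE libraries, including DPYSL4 (32 and 47 in shControl), MCAM (35 and 25), an adhesion molecule, and GYG2 (23 and 37), glycogenin 2. The symbols SPECC1L-ADORA2A (54 and 191 in shControl, listed at 0 in shMIRE), GET1-SH3BGR (63 and 80 in shControl, listed at 0 in shMIRE) and RPL36A-HNRNPH2 (1129 and 635 in shControl, 40 and 11 in shMIRE) are read-through genes that overlap the genes in their names, so how reads were divided between them is uncertain. The fall of RPL36A-HNRNPH2 did not pass with limma without shControl replicate 1 or 2 (adjusted p = 0.0716 and 0.0577), and the rise of KCNF1 did not without shMIRE replicate 2 (0.0596).

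Genes lower in shMIRE differed from genes higher in it in their 3′ UTRs, a comparison made after the data were seen. The heptamer GCTGTGT was present in 289 of 704 genes lower (41.1%) and in 84 of 459 genes higher (18.3%). Among the lower genes named above, SLC7A5, TPI1, TRIB3, FEN1, CCND1, EBP, OAS3, SRM, POLA1, CDC25A, TXNRD1, ACSL3, ATG9A, CTSL, IGF2BP1, FLT1 and GYG2 carried it. About as many did not: NDRG1, DDIT4, IDI1, ELF3, NDUFB8, TIMP3, SLC7A11, OAS2, OASL, LRP2, PDPN, H2AC6, H2BC21, DPYSL4, MCAM, GET1-SH3BGR and RPL36A-HNRNPH2. Of the higher genes, BTG2 and CLDN1 carried it, and 0 of the 12 NF-kB genes did.

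**Figure D3:**
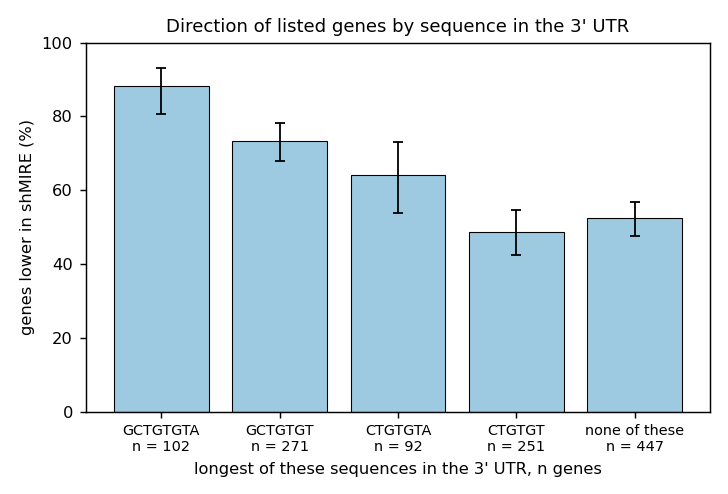
Bars give the percent of listed genes that were lower in shMIRE, with 95% Wilson intervals, for genes grouped by the longest of 4 nested sequences in their 3′ UTR; n is the number of genes. The percent was 88.2 for genes with GCTGTGTA, 73.4 for the other genes with GCTGTGT and 52.3 for genes with none of the sequences.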

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

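Scaling to equal sums of the listed values was the alternative chosen after the data were seen. The number of genes past the threshold (1147 with limma) stayed within 1.5 times under every alternative run. It was 1000 with quantile normalisation (455 up, 545 down), 1124 with libraries scaled to equal sums of the listed values (458 up, 666 down), 1104 without the intensity trend, 1116 with a mean above 5 (1135 genes tested), 1116 with a pseudocount of 0.1, 920 at an adjusted p under 0.01, and 827 to 900 with 1 library left out, where the lone library is assumed to vary like the other group. Quantile normalisation and equal sums raised the median log2 fold change of all genes by 0.32 and 0.30; 0 genes changed sign under either. Of the 82 named genes, 63 kept their call without each library in turn. Of 8 lists, 4 passed with camera, 0 with an estimated correlation, 8 with fry, which does not compare a list with other genes, and 1 at 0.01. The choice of genes for their difference made a pass with fry likely beforehand, so it adds no support. The estimated correlation was -0.0210 for NF-kB, -0.193 for the epithelial-mesenchymal transition, -0.166 for YAP/TEAD and 0.651 for extracellular matrix. For the lists below the preset 0.01, these values argue against a higher correlation between genes as the cause of the loss. The NF-kB camera p, unadjusted, went from 1.1e-05 to 0.043 although its estimate lay below the preset. With an estimated correlation camera also tests on the few residual degrees of freedom of 4 libraries, and with the preset it does not. The loss is therefore not evidence of correlation in these lists, and other causes were not tested. The TGF-beta list passed with the replicate number as a block (camera adjusted p = 0.0290) and with equal sums (0.0452), and its range over the camera alternatives was 0.0290 to 0.448. Without shControl replicate 1, 1 gene changed sign. With the replicate number as a block, 1175 genes and 5 lists passed; deviations of equally numbered libraries correlated at 0.0321 across genes, so the numbers were not taken as pairs. The count tests and their scalings were not run because the values look already scaled, which was not settled; no filter, no rescaling and the choice of genes in the tables left the values as they were, and a fold threshold does not apply to camera. Depth limits are unknown without library totals.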

Other observations

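The tests in this part were chosen after the result they bear on was seen, except those of the sites of 20 microRNA families, which were fixed before their scores were seen. The genes below were chosen after their values were seen. HMGA2, an architectural chromatin protein of embryonic and tumour cells, rose from 2993 ± 208 in shControl to 27775 ± 636 in shMIRE (SD, n = 2), 9.28-fold. The leukocyte integrin gene ITGB2 rose 3.48-fold to 26340 ± 1085, CSF1, the macrophage growth factor, 2.78-fold to 26692 ± 1197, and the complement gene C3 2.01-fold to 15371 ± 1592. Collagen genes went largely one way: of 9 listed genes whose symbols are COL followed by a number, 8 were higher and 1 was lower, the only difference in direction to pass among 14 families of symbols with the same letters before the first digit and at least 5 listed genes (Fisher's exact test, two-sided, p = 0.00327, Benjamini-Hochberg adjusted p = 0.0458). Of the 9, only COL20A1 carried GCTGTGT, and the family was not compared with other genes without that heptamer. In that comparison the matrix list, which shares COL1A1, COL5A1 and COL6A3 with the family, did not pass (Fisher's exact test, adjusted over 4 lists, 0.0767). Among abundant lower genes, ATP1B1, the beta subunit of the sodium pump, fell 3.83-fold, the small GTPase gene RHOB 3.24-fold, the chaperonin gene CCT5 3.12-fold and HMGB1, a chromatin protein, 2.86-fold. Of the clathrin adaptor subunits, AP1B1 fell 7.52-fold, AP1M2 2.77-fold, AP2B1 2.54-fold, AP1G1 2.22-fold and AP2A1 2.12-fold. These subunits were picked after their values were seen and not tested as a group. Each of them, and ATP1B1, RHOB, CCT5 and HMGB1, carried the heptamer GCTGTGT in the 3′ UTR. Of the higher genes HMGA2, ITGB2, CSF1 and C3, only CSF1 carried it.

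GCTGTGT had a Mantel-Haenszel z over strata of 3′ UTR length of 9.78, against a largest absolute z of 5.79 over all heptamers in 1000 permutations of direction (permutation p = 0.001, the smallest they can give), and it ranked first in both random parts of the genes (z of 7.26 in 581 genes and 6.41 in 582). The values argue against length and GC percent of the 3′ UTR as the whole of it. With length, GC percent and mean value in a logistic model the odds ratio of being lower was 4.82 (95% interval 3.51 to 6.62). That interval does not allow for the choice of this heptamer by its z in the same genes. The median z of 121 heptamers of the same composition was 0.565. That 0 of them had a z as large follows from choosing the heptamer with the largest z, so it is no evidence. A candidate explanation is a small RNA with the seed ACACAGC that lowers its targets in shMIRE cells: 88.2% of genes with GCTGTGTA, 73.4% of the others with GCTGTGT, 64.1% with CTGTGTA, 48.6% with CTGTGT alone and 52.3% with none were lower, so that the shortest site showed no excess, while in the coding sequence and the 5′ UTR the z was 0.33 and -0.06. Whether that RNA may be the guide strand of the hairpin or an endogenous microRNA set free by the loss of MIRE cannot be told apart here, since the hairpin sequence was not used. Of 4 annotated transcripts of SAP30-DT, taken here as MIRE, 1 carries GCTGTGT (chromosome 4, 173368052 to 173368058, minus strand, in its single exon, context TTCTTAATGCTAGAGCTGTGTGCCC), but so do 22.2% of long non-coding transcripts of that length. The sequence ACACAGC occurs somewhere in 6 of 1881 annotated microRNA hairpins. Whether it is the seed of a mature microRNA in any of them was not examined, nor was the number that chance would give.

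The heptamer and direction were also compared within 4 ranges of abundance, with Fisher's exact test, two-sided, adjusted over the 4. Among genes with a mean value of 1935 or more, 83.1% of genes with the heptamer and 36.4% of those without were lower (adjusted p = 8.5e-16). From 406 to 1921 the shares were 79.1% and 41.7% (adjusted p = 6.1e-10), from 60 to 405.5 they were 59.7% and 54.4% (adjusted p = 0.475), and from 3.5 to 59.5 they were 79.2% and 68.6% (adjusted p = 0.182). Whether the ranges differ from one another was not tested. GCTGTGT was chosen for its largest z in these same genes, and these p-values do not allow for the choice among 16384 heptamers. Against the other 17914 protein-coding genes of the annotation, matched in strata of 3′ UTR length, the odds ratio of carrying it was 3.65 for genes lower and 0.775 for genes higher.

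Genes higher in shMIRE had longer and more AU-rich 3′ UTRs, with a median of 1656 bases against 1289.5 in genes lower (permutation p = 0.00032) and 42.2% GC against 46.1% (permutation p = 8.0e-05). The heptamer most tied to them was TGCAATA, the site of the miR-25/92 family (z -5.14). Sites of 20 other microRNA families were fixed before their scores were seen, and the levels of these families in the cells were not analysed here. Of the 20, 6 lay in the lowest 5% of z among heptamers of their own base composition. Random placement would give 1 (exact one-sided binomial p = 0.000329). The median of the 20 lay at 22.1%, so the sites were shifted as a set. Those heptamers are matched in base counts and not in base order, so the count cannot exclude base composition of the 3′ UTRs as the cause. The sites of miR-19, miR-21 and miR-17 were among the 6 and that of let-7 was not. Competition of the candidate small RNA, if it exists, with microRNAs of the cell for the silencing machinery may give this pattern, as an untested hypothesis. Both groups received a hairpin, so competition from a hairpin as such would be shared and would not by itself separate them. A general richness of regulatory sites in the higher genes was not separated from such competition. Some sites share bases, so they are not independent.

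The rise of all 12 listed NF-kB genes was set against the same sequence. If it only reflected a background full of genes lower with the heptamer, it would vanish among genes without it; there, 12 of 12 NF-kB genes were higher against 46.7% of 778 other genes (Fisher's exact test, two-sided, p = 0.000119, adjusted over 4 lists 0.000477). In the same exact test the epithelial-mesenchymal list had an adjusted p of 0.0475, and extracellular matrix and YAP/TEAD targets did not pass (0.0767 and 0.107). This test takes genes as independent. The NF-kB and epithelial-mesenchymal lists each had a camera adjusted p = 0.316 with an estimated correlation, where the estimates were -0.0210 and -0.193. An interferon response to the virus or the hairpin would be a possible explanation for inflammatory genes, and of the 3 listed interferon genes 0 rose, but OAS3 and OASL carry GCTGTGTA and CTGTGTA, and OAS2, the 1 gene without a site of that length, is a low gene whose limma adjusted p was 0.0621 and 0.0805 without shMIRE replicate 1 or 2 and 0.0833 with quantile normalisation, so these genes are too few to exclude it. Both groups received a lentivirus and a hairpin, so a response common to both would not by itself give a difference between them. A change in NF-kB signalling through the loss of MIRE, or as a later effect of the genes lower with the heptamer, stays open as untested.

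With MIRE taken as SAP30-DT, listed genes were not near it: of 43 on chromosome 4, 0 lay within 1 Mb, and the nearest, CPE, lay 7.85 Mb away. A few values rested on a single library. ZNF593 stood at 442 in shControl replicate 1 and at 0 in the other 3 libraries, PEDS1-UBE2V1 at 903 in shMIRE replicate 1 and BLOC1S5-TXNDC5 at 612 in shMIRE replicate 2, each at 0 elsewhere; none of these 3 passed with limma (adjusted p of 0.189 for each). In all, 12 listed symbols name read-through genes, 4 of them at 0 in at least 1 library.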
